A study of Mus musculus with 13 samples.

How the data were processed

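RNA from sorted erythroid cells of 6 mouse embryos was labelled with biotin and measured on 13 arrays, 1 for each embryo and sorted population. The values used are log2 signals as deposited, which the authors had made with RMA per the submitters' processing notes. RMA corrects background, quantile-normalizes and summarizes over probes. The version of the RMA software was not given in the sources used here. The notes also name the mm9 genome build without stating its role. No scanner files were used here, so background correction was not redone. The deposited table holds 35556 probe sets, and its values run from 1.62 to 13.5. All 13 value columns were used, and the only limit on precision named here is the number of arrays.

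Gene symbols came from the platform's gene table. Of the probe sets, 21789 were listed with exactly 1 symbol, 1621 with several symbols and 12146 with no listed gene. Those with several or no symbols were left out of the gene tests and were tested apart as unused data. For 999 genes with more than 1 probe set, the probe set with the highest mean over all arrays was kept, which left 19938 genes. All probe sets with 1 symbol were also fitted apart, and genes with several probe sets of which at least 1 was called there were examined. Of 28 such genes in Ter119- CD71+ cells 3 had probe sets of opposite sign, and in 9 all probe sets were called. Of 42 in Ter119+ CD71+ cells 5 had opposite signs, and in 19 all were called.

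Samples were grouped by genotype and sorted population as the labels give them. limma 3.58.1 under R 4.3.3 was fitted to all 13 arrays with 5 group means, which left 8 residual degrees of freedom, and eBayes added 5.56 prior degrees of freedom with a prior SD of 0.158. The 6 comparisons were knockout against control in each of the 2 populations, the difference between these effects, the 2 maturation steps in controls and the 1 in knockouts. P values were two-sided and adjusted by the Benjamini-Hochberg method over all genes, and a gene was called at an adjusted p under 0.05. The comparisons, tests, named-gene rule, alternatives and 24 gene lists were chosen before the data were examined.

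The named genes were Adar, then the 10 largest changes in each direction in each knockout comparison and the 6 largest in each maturation comparison, among called genes whose arrays did not overlap between groups. To these were added the 5 largest in each direction for the interaction and up to 4 members of each list with the smallest adjusted p. The text gives values for part of these. Predicted genes were to be passed over, and 0 had to be.

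Of the 24 lists, 23 were tested as sets with camera at a preset correlation between genes of 0.01, then with an estimated correlation and with fry, adjusted over the lists within each comparison. The other, of sex-linked genes, had 4 measured members and served only to check embryo numbers. Of 138 tests, 63 were called with the preset correlation. Of these, 3 also passed with an estimated correlation, and they were the late erythroid list in both steps to Ter119+ CD71+ cells and the globin list in the knockout step. fry, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes, called 35 of the 63. The mean, the median and the camera direction of a list differed in sign in 22 of the 138.

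The embryo number in the sample titles links populations of 1 embryo, and the design text says that each sample came from 1 mouse. The sex-linked genes separated the numbers in the same way in every population. After the group means were removed, arrays of the same embryo correlated between -0.23 and 0.35 over 9 pairs, 4 of them above 0.1, and arrays of different embryos between -0.38 and 0.27. The consensus correlation was 0.00385, so embryo was not a term in the fits reported, and it was tried as a block. No embryo number links a knockout with a control.

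Positions on the maturation axes were projections of each array on the control difference, compared by exact two-sided permutation tests over arrays. Correlations across genes carry no p, since genes are not independent replicates. A range of r to set beside them came from 100 data sets simulated without an effect. Their noise was drawn independently between genes, so that range leaves out correlation between genes and can be too narrow. The alternatives were quantile normalization again, median centring, leaving out the lowest 33.3% of genes, the mean of all probe sets, an intensity trend with robust eBayes, only the groups compared, array weights, embryo as a random or fixed block, a minimum log2 fold change of 1, the R26 EYFP genotype as a covariate and leaving out each array in turn. A covariate made of the myeloid marker mean was added after the values were seen. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

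The fits were tested on simulated data with 200 changed genes of 19938 in each of 5 draws, with noise drawn independently between genes. For Ter119- CD71+ cells, 26.6%, 85.4% and 99.1% of changes of 0.5, 1 and 2 log2 units were found, and 4.49% of calls were false. For Ter119+ CD71+ cells the shares were 23.6%, 81.5% and 97.9%, with 6.38% false. For the interaction they were 3.88%, 57.3% and 94.8%, with 6.33% false. For the first control step they were 32.8%, 90.4% and 99.7%, with 4.63% false, for the second 25.4%, 84.2% and 97.6%, with 5.75% false, and for the knockout step 17.6%, 81.5% and 99.7%, with 3.78% false. A list shifted by 0.5 was found in 5 of 5 draws in every comparison, and between 1 and 3 of 110 tests of unshifted lists were called. Without correlation between genes in the noise, these list counts do not show how often lists of correlated genes are falsely called.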

Results

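Gene expression was measured with 13 single-colour, biotin-labelled arrays on erythroid cells sorted by flow cytometry from the fetal livers of 6 mouse embryos at E14.5. Adar encodes ADAR1, an enzyme that converts adenosine to inosine in double-stranded RNA. In the knockout embryos (numbers 1, 10 and 11) 1 Adar allele was floxed and the other was null. In the control embryos (numbers 2, 13 and 15) 1 allele was floxed and the other intact. All 6 carried Cre recombinase at the erythropoietin receptor locus, which is active in the erythroid lineage. The sorts used Ter119, an antigen of maturing erythroid cells, and CD71, the transferrin receptor. Ter119- CD71+ cells were profiled from 3 knockout and 3 control embryos, the more mature Ter119+ CD71+ cells from 2 knockout embryos (10 and 11) and 3 controls, and Ter119+ CD71med cells from 2 controls (13 and 15). The R26 EYFP allele, a Cre reporter, was present in all 3 control embryos and in knockout embryo 1, and absent from knockout embryos 10 and 11. Array medians lay between 5.66 and 5.89 log2 units, and the number of arrays limits the precision. Arrays stood apart in 2 groups. The Ter119+ CD71+ arrays of knockout embryos 10 and 11 differed by a median of 0.2465 log2 units per gene, and the 2 Ter119+ CD71med arrays by 0.2049, against 0.1123 to 0.178 between arrays of the groups of 3. The upper quartile of the array of embryo 10 was 7.415, near the 7.41 and 7.30 of the Ter119+ CD71med arrays, and that of embryo 11 was 7.63, where the control Ter119+ CD71+ arrays had 7.51 to 7.53.

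The targeted gene was examined first. Adar, represented by 1 probe set on chromosome 3, was not lower in the knockout cells on these arrays. Its level was 7.52 ± 0.13 in knockout and 7.60 ± 0.34 in control Ter119- CD71+ cells (mean log2 ± SD, n = 3 each), a difference of -0.08 (SE 0.23, adjusted p = 0.951). The Ter119+ CD71+ cells had 7.89 ± 0.29 (n = 2) against 7.84 ± 0.48 (n = 3), a difference of 0.05 (SE 0.25, adjusted p = 0.973). The sign is not determined: without control embryo 13 or 15 the first difference was 0.02 or 0.01, and the second was -0.16 without control embryo 2 or knockout embryo 11 and -0.01 without control embryo 13, and also on median-centred arrays. Control Ter119+ CD71med cells had 8.32 ± 0.30 (n = 2). Where the probes lie relative to the floxed exons is not given in the sources used here, so the probe set is no check of the genotype labels. The female-expressed Xist transcript and the Y-linked genes Eif2s3y, Kdm5d and Uty separated the embryos the same way in every population profiled. Xist was 4.06 to 5.31 in embryos 1 and 15 and 10.88 to 11.75 in embryos 2, 10, 11 and 13. Eif2s3y was 8.28 to 8.93 in the first pair and 2.80 to 3.14 in the other 4. Among the knockout embryos these genes and the R26 EYFP allele split the same way, embryo 1 against embryos 10 and 11. Comparisons by EYFP among the knockouts therefore also compare the sexes. In Ter119+ CD71+ cells both knockout embryos had high Xist, and control embryo 15 did not.

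In Ter119- CD71+ cells, the less mature population, knockout was compared with control. This asks what loss of Adar changes early in erythroid maturation, against controls with 1 floxed and 1 intact allele. Interferon-stimulated genes led the increases. Trim30a, an interferon-induced tripartite motif gene, rose by 4.45 log2 units (SE 0.24, n = 3 each, adjusted p = 2.78e-07). Sp100, a nuclear body component, rose by 3.49 (SE 0.15, adjusted p = 5.93e-08), Ifi27 by 3.51 (SE 0.34, adjusted p = 8.03e-05) and Lgals3bp by 2.72 (SE 0.20, adjusted p = 5.44e-06). The amino acid transporter genes Slc7a11 and Slc7a3 rose by 3.34 (SE 0.20) and 3.29 (SE 0.18). Among the decreases were Serpina6, which encodes corticosteroid-binding globulin, at -1.99 (SE 0.28, adjusted p = 0.00266), the embryonic globin gene Hbb-bh1 at -1.79 (SE 0.29, adjusted p = 0.00677), the transcriptional corepressor gene Runx1t1 at -1.63 (SE 0.18, adjusted p = 0.000244) and Hsd3b6 at -1.29 (SE 0.22, adjusted p = 0.00922).

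Of 54 measured interferon-stimulated genes, 24 rose, 0 fell and 30 did not pass, and 31 rose when adjusted over the list alone. The list mean was 0.92 higher in knockout Ter119- CD71+ cells (camera adjusted p = 8.99e-33; adjusted p = 0.0580 with an estimated correlation), and all 3 knockout arrays lay above all 3 control arrays. The list mean per array was 6.96 ± 0.11 in knockout and 6.05 ± 0.15 in control cells (SD, n = 3 each). Of 22 genes of the cytosolic RNA-sensing pathway 3 rose, all of them also in the interferon list: Ifih1 by 1.49 (SE 0.30), Ddx58 by 1.43 (SE 0.26) and Dhx58 by 1.20 (SE 0.20), which encode the helicase sensors MDA5, RIG-I and LGP2. This list as a whole was not called (adjusted p = 0.240), and the calls of Ifih1 and Ddx58 ended without knockout embryo 10 or control embryo 13 (highest adjusted p 0.102 and 0.0599). The interferon and interferon receptor list was not called either (adjusted p = 0.370), with Ifnar2 as its only member called, at 0.58 (adjusted p = 0.0102, and 0.0703 without knockout embryo 10). In the RNA-editing list Apobec1, a cytidine deaminase gene, rose from 5.97 ± 0.18 to 7.97 ± 0.37 (SD, n = 3 each, adjusted p = 3.78e-05), while the list's mean was 0.10, its median -0.08 and its test pointed down (adjusted p = 0.860).

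The integrated stress and unfolded protein response list rose with a mean of 0.46: 6 of 29 genes rose, 0 fell and 23 did not pass, with 9 higher when adjusted over the list alone (camera adjusted p = 6.12e-07; adjusted p = 0.0780 with an estimated correlation). Besides Slc7a11, its leading members were Nupr1 at 2.58 (SE 0.23), Chac1, a glutathione-degrading enzyme, at 1.68 (SE 0.20) and the pseudokinase gene Trib3 at 1.49 (SE 0.19). The p53 and apoptosis list was not called in these cells (0 of 31 genes, mean -0.03, adjusted p = 0.674), nor were ribosomal proteins (0 of 45, adjusted p = 0.330) or antigen presentation (0 of 14, 2 higher and 1 lower when adjusted over the list alone, adjusted p = 0.0587). limma called 0 genes in these 3 lists, where it called 441 of all 19938 genes (2825 at an unadjusted p under 0.05).

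Cell cycle and erythroid lists were lower in knockout Ter119- CD71+ cells. Part of these calls ended when the mean of the myeloid markers was fitted as a covariate. That mean was itself 0.98 higher in these knockout cells, so fitting it also costs precision in the knockout effect. A call that ended does not show that myeloid cells account for it. The G1/S list had a mean of -0.33 with 4 of 27 genes lower and 0 higher, and 13 lower when adjusted over the list alone (camera adjusted p = 2.86e-11; adjusted p = 0.347 with an estimated correlation). Its called members were Ccne1 (cyclin E1) at -0.84 (SE 0.18), the flap endonuclease gene Fen1 at -0.68 (SE 0.15), the ribonucleotide reductase gene Rrm2 at -0.51 (SE 0.12) and the thymidylate synthase gene Tyms at -0.41 (SE 0.10). These 4 calls ended without knockout embryo 1, knockout embryo 10, control embryo 13 or control embryo 15, with adjusted p up to 0.160, 0.202, 0.248 and 0.278, and that of Tyms also without control embryo 2 or knockout embryo 11. In the G2/M list 1 of 27 genes fell, Kif20a at -0.62 (7 lower when adjusted over the list alone; mean -0.16, adjusted p = 0.00184; adjusted p = 0.430 with an estimated correlation), and its call was kept only without control embryo 2 (highest adjusted p 0.170). With the myeloid marker mean as a covariate the G2/M list had a mean of -0.0224, its test pointed up and it was not called (adjusted p = 0.907), while G1/S stayed called.

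Of 20 red cell membrane genes 3 fell and 0 rose, against 7 lower and 1 higher when adjusted over the list alone (mean -0.26, adjusted p = 3.08e-05; adjusted p = 0.393 with an estimated correlation). They were the cytoskeletal genes Dmtn at -0.82 (SE 0.14) and Epb42 at -0.62 (SE 0.13), and Cldn13 at -0.80 (SE 0.19). Heme synthesis and iron genes had 4 lower and 1 higher of 18, and 10 lower and 1 higher when adjusted over the list alone (mean -0.21, adjusted p = 0.000552; adjusted p = 0.368 with an estimated correlation). Uros at -0.64 and Urod at -0.49, which encode enzymes of the heme pathway, fell, and so did Steap3 at -0.77, whereas Hmox1, the heme-degrading oxygenase, rose by 1.80 (SE 0.18, adjusted p = 0.000103). Among erythroid transcription factors 2 of 20 fell, E2f4 at -0.75 and E2f2 at -0.54, with 8 lower and 1 higher when adjusted over the list alone (mean -0.22, adjusted p = 0.00103; adjusted p = 0.368 with an estimated correlation). The calls of Dmtn and Epb42 ended without knockout embryo 10, control embryo 13 or control embryo 15 (highest adjusted p 0.0571 and 0.174). Those of Cldn13, Uros, Urod, Steap3, E2f4 and E2f2 ended in each omission except that of control embryo 2, with adjusted p up to 0.244, 0.195, 0.175, 0.183, 0.200 and 0.254. With the myeloid covariate the heme list was not called (adjusted p = 0.114), and the membrane and transcription factor lists were.

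Of 6 measured globin genes Hbb-bh1 and Hba-x fell, by 1.79 and 0.90, and Hbq1b rose by 0.62, with 3 lower and 1 higher when adjusted over the list alone. The list mean was -0.60 (adjusted p = 0.0149, and 0.161 without control embryo 2; adjusted p = 0.368 with an estimated correlation). Hbq1b was not called without knockout embryo 1, knockout embryo 10, control embryo 13 or control embryo 15 (highest adjusted p 0.147). The adult globin genes share probe sets or are unlisted and were not analysed here. The late erythroid maturation list had a mean of -0.17 in knockout Ter119- CD71+ cells, with Ypel4 (-0.99) and Acp5 (-0.73) lower and Tspo2 (0.43) higher among 24, and 3 lower and 2 higher when adjusted over the list alone (adjusted p = 0.0149; adjusted p = 0.368 with an estimated correlation). That call ended without control embryo 15 (adjusted p = 0.0669) and on arrays quantile-normalized again. Acp5 and Tspo2 each lost their call in 5 of 6 omissions (all except that of control embryo 2 for Acp5 and of knockout embryo 11 for Tspo2; highest adjusted p 0.223 and 0.242). The Ypel4 call ended without knockout embryo 10 or 11 or control embryo 13 or 15 (highest adjusted p 0.129). The early progenitor list was 0.12 higher with 0 of 22 members called (adjusted p = 0.0387; adjusted p = 0.401 with an estimated correlation), and its call ended without control embryo 2, knockout embryo 10 or control embryo 15 (highest adjusted p 0.183). With the myeloid marker mean as a covariate the early progenitor mean turned to -0.0332 (adjusted p = 0.907), and the globin and late erythroid lists were not called (adjusted p = 0.132 and 0.439).

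Markers of another cell type moved with these groups. The neutrophil and myeloid list was 0.98 higher in knockout Ter119- CD71+ cells: 4 of 19 genes rose and 0 fell, and 12 rose when adjusted over the list alone (adjusted p = 2.27e-11; adjusted p = 0.360 with an estimated correlation). The 4 called genes were Mpo (myeloperoxidase) at 2.44 (SE 0.40), S100a9 at 2.74 (SE 0.54), Ms4a3 at 1.26 (SE 0.29) and Fcnb at 1.24 (SE 0.23). S100a9 lost its call without control embryo 13 or 15, Ms4a3 without any 1 of the 3 controls and Fcnb without control embryo 15 (highest adjusted p 0.0773, 0.167 and 0.0721). The list mean was 6.98 in knockout embryo 10, 5.76 in embryo 1, 5.71 in embryo 11 and between 5.03 and 5.41 in the controls. The macrophage list was 0.28 higher (1 of 18, Hmox1, called; 3 when adjusted over the list alone; adjusted p = 0.0149, and 0.162 without control embryo 2; adjusted p = 0.368 with an estimated correlation), and it was not called with the myeloid covariate (adjusted p = 0.265). The hepatocyte list was lower (mean -0.20) with 0 of 19 called and 2 lower when adjusted over the list alone (adjusted p = 0.0328; adjusted p = 0.479 with an estimated correlation), a call that ended without knockout embryo 1 or 11 or control embryo 2 or 15 (highest adjusted p 0.134). Lymphoid, mast cell, endothelial and megakaryocyte markers were not called (0 members each, 1 megakaryocyte gene higher when adjusted over the list alone; adjusted p = 0.323, 0.370, 0.446 and 0.681).

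In all, limma called 441 of 19938 genes between knockout and control Ter119- CD71+ cells, 270 higher and 171 lower. The arrays of all 441 did not overlap between genotypes, as did those of 21.5% of all genes, where chance gives 10% for 3 arrays against 3. The count was 241 without knockout embryo 1, 136 without knockout embryo 10, 148 without control embryo 13 and 135 without control embryo 15. Without control embryo 2 it was 1006 and most were lower (376 higher and 630 lower), as with array weights (1308 higher and 1843 lower), so the prevailing direction among called genes is not settled. With the R26 EYFP genotype as a covariate, which leaves the knockout effect resting on embryo 1, 33 genes were called (30 of them shared), and with the mean of the myeloid list as a covariate, an alternative chosen after the values were seen, 25 (24 shared). Trim30a, Rtp4, Sp100, Slc7a11, Slc7a3, Ifi27 and Lgals3bp were called under both. Sex-linked genes also set embryo 1 apart from embryos 10 and 11, so among the knockouts the EYFP allele and sex cannot be told apart. The myeloid mean is itself higher in the knockout cells, so fitting it costs precision in the knockout effect. Some genes lost the call with it at folds near their size, as did Serpina6 at -1.98 (adjusted p = 0.253). Others shrank, as did Hbb-bh1 from -1.79 to -0.87 (adjusted p = 0.755). With the EYFP covariate the interferon-stimulated list went from 0.92 (SE 0.135) to 0.85 (SE 0.201), the stress list from 0.46 (SE 0.0594) to 0.50 (SE 0.0879) and the myeloid list from 0.98 (SE 0.311) to 0.59 (SE 0.421). For Ter119+ CD71+ cells the myeloid list went from 0.05 (SE 0.348) to -0.54 (SE 0.557).

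**Figure D1:**
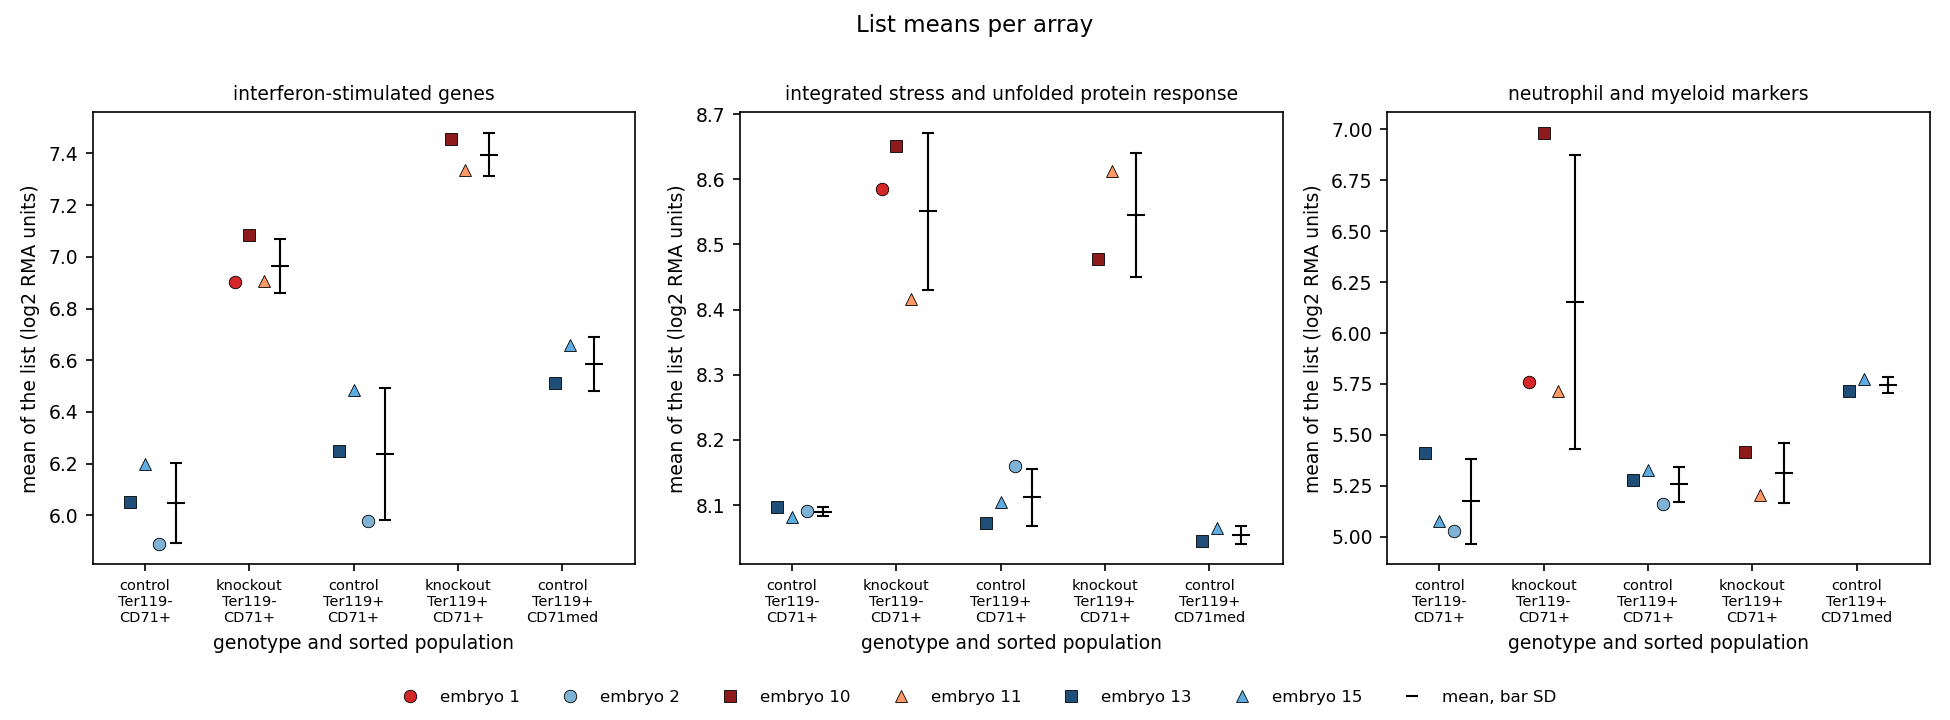
Mean of 3 gene lists on each array in log2 units, by genotype and sorted population; points are arrays marked by embryo, and bars are the group mean with its SD. The interferon-stimulated list lies between 6.90 and 7.46 in the 5 knockout arrays and at 6.66 or lower in the 8 control arrays, and the myeloid marker list reaches 6.98 in knockout embryo 10.

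In Ter119+ CD71+ cells, the same question was asked of the more mature population, and interferon-stimulated genes again led the increases. Trim30a rose by 5.04 (SE 0.27, adjusted p = 3.14e-07), Sp100 by 4.77 (SE 0.17, adjusted p = 4.12e-09), Rtp4 by 4.69 (SE 0.23, adjusted p = 1.22e-07), Samd9l, an antiviral restriction factor gene, by 3.92 (SE 0.28, adjusted p = 5.85e-06), Gbp7 by 3.10 (SE 0.28) and Oasl2 by 3.06 (SE 0.33). Sp100 measured 9.94 ± 0.04 in knockout (n = 2) and 5.17 ± 0.26 in control cells (n = 3). Slc7a11 and Slc7a3 rose by 3.89 (SE 0.22) and 3.16 (SE 0.20). The largest decreases included Hsd3b6 at -2.35 (SE 0.25, adjusted p = 0.000188), Runx1t1 at -2.19 (SE 0.20, adjusted p = 4.11e-05), the fatty acid translocase gene Cd36 at -2.15 (SE 0.28, adjusted p = 0.000811), Serpina6 at -1.97 (SE 0.32, adjusted p = 0.00456) and Gpr155 at -1.85 (SE 0.25, adjusted p = 0.00122).

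Of the 54 interferon-stimulated genes 22 rose, 1 fell and 31 did not pass in Ter119+ CD71+ cells, with 29 higher and 1 lower when adjusted over the list alone. The list mean was 1.16 higher (camera adjusted p = 1.03e-30; adjusted p = 0.0653 with an estimated correlation), at 7.40 ± 0.08 in knockout (n = 2) and 6.24 ± 0.25 in control cells (n = 3). The member that fell was Ube2l6, a conjugating enzyme for ISG15, at -0.68 (adjusted p = 0.0405). It lies outside the naming rule and was chosen after its value was seen. RNA-sensing genes had 3 of 22 higher, with 1 lower when adjusted over the list alone (mean 0.24, adjusted p = 0.0378; adjusted p = 0.216 with an estimated correlation): Ddx58 at 1.62 (SE 0.29), Ifih1 at 1.48 (SE 0.33) and Dhx58 at 1.45 (SE 0.23). Ddx58 and Ifih1 lost their calls without knockout embryo 10 (adjusted p = 0.147 and 0.237). The list lost its call without knockout embryo 11 or control embryo 13 (highest adjusted p 0.263) and on arrays quantile-normalized again. The RNA-editing list was 0.36 higher with Apobec1, at 2.25, as its only member called (adjusted p = 0.0435; adjusted p = 0.175 with an estimated correlation). That list was not called without control embryo 2, knockout embryo 11 or control embryo 13 (highest adjusted p 0.200) or on arrays quantile-normalized again. The interferon and receptor genes themselves were not called (0 of 13, adjusted p = 0.369). In antigen presentation, not called as a list (adjusted p = 0.0866), the light chain gene B2m rose by 0.65, a call lost without control embryo 2, knockout embryo 10 or control embryo 15 (highest adjusted p 0.226).

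The stress response list was 0.43 higher in knockout Ter119+ CD71+ cells, with 4 of 29 genes higher and 0 lower, 7 higher when adjusted over the list alone (adjusted p = 0.000125, and 0.200 without knockout embryo 11; adjusted p = 0.175 with an estimated correlation). Besides Slc7a11 these were Nupr1 at 2.60 (SE 0.25), Chac1 at 1.55 (SE 0.22) and Trib3 at 1.41 (SE 0.21). Late erythroid maturation genes had a mean of -0.31 with 2 of 24 lower and 0 higher, 8 lower when adjusted over the list alone (adjusted p = 3.12e-08; adjusted p = 0.0653 with an estimated correlation). They were Xpo7, an exportin gene active in terminal erythroid maturation, at -1.18 (SE 0.17) and Trim10 at -0.78 (SE 0.18). Red cell membrane genes had a mean of -0.38 with 1 of 20 lower, the water channel gene Aqp1 at -0.86, and 8 lower when adjusted over the list alone (adjusted p = 1.36e-10; adjusted p = 0.175 with an estimated correlation). Trim10 lost its call in each omission except that of knockout embryo 11, and Aqp1 in each except that of control embryo 13 (highest adjusted p 0.377 and 0.255). The G2/M list had a mean of -0.28 (camera adjusted p = 2.27e-10, and 0.175 with an estimated correlation). Of its 27 genes limma called 0, where it called 510 of all 19938 genes (2572 at an unadjusted p under 0.05). When adjusted over the list alone, 6 were lower.

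Heme genes had a mean of -0.25 with Hmox1 higher by 1.31 (SE 0.20) and 0 of 18 lower, 6 lower when adjusted over the list alone (adjusted p = 1.62e-05, and 0.0507 without knockout embryo 10; adjusted p = 0.219 with an estimated correlation). The G1/S list had a mean of -0.18 with 0 of 27 called, also when adjusted over the list alone (adjusted p = 0.000102, and 0.476 without knockout embryo 10; adjusted p = 0.404 with an estimated correlation). Among erythroid transcription factors Nfe2, the gene of the p45 subunit of NF-E2, fell, by 0.74 (adjusted p = 0.0107, and 0.148 without knockout embryo 10), and 7 of 20 were lower when adjusted over the list alone (mean -0.19, adjusted p = 0.00262, and 0.0780 without knockout embryo 10; adjusted p = 0.354 with an estimated correlation). On arrays quantile-normalized again these last 2 lists were not called. Myc, in the early progenitor list, rose by 0.90 (SE 0.14, adjusted p = 0.00456), and that list was not called (adjusted p = 0.155). Hbb-bh1 fell by 1.77 (SE 0.33, adjusted p = 0.0107, and 0.164 without knockout embryo 10), while the globin list was not called and had a mean of -0.11 and a median of 0.13 (adjusted p = 0.895). The p53 and apoptosis list (0 of 31) had a mean of 0.08 and a median of -0.02 (adjusted p = 0.425), and ribosomal proteins (0 of 45) were not called (adjusted p = 0.629).

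Neutrophil and myeloid markers differed by 0.05 in Ter119+ CD71+ cells, with 0 of 19 called (adjusted p = 0.895). Hepatocyte markers were lower in knockout cells (list mean -0.38), with 1 of 19 lower, Apoa1 at -0.60, and 8 lower when adjusted over the list alone (adjusted p = 4.72e-07, and 0.0897 without knockout embryo 11; adjusted p = 0.175 with an estimated correlation). Apoa1 was not called in any omission except that of knockout embryo 10 (highest adjusted p 0.0919). Egfl7, in the endothelial list, rose by 0.53 (SE 0.12), a call lost without control embryo 2, knockout embryo 10, knockout embryo 11 or control embryo 13 (highest adjusted p 0.0856). Macrophage, megakaryocyte, lymphoid, endothelial and mast cell lists were not called, with Hmox1 the only member of the macrophage list that rose (adjusted p = 0.136, 0.384, 0.424, 0.569 and 0.699).

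In all, limma called 510 genes between knockout and control Ter119+ CD71+ cells, 295 higher and 215 lower. The arrays of all 510 did not overlap, as did those of 22.1% of all genes, where chance gives 20% for 2 arrays against 3. The count was 309 without control embryo 2 and 294 without control embryo 15. With only the groups compared it was 116 (90 higher and 26 lower), and with array weights 128 (91 higher and 37 lower). It was 162 without knockout embryo 10 (135 higher and 27 lower) and 1546 without knockout embryo 11 (592 higher and 954 lower), so the prevailing direction depends on which of the 2 knockout arrays is kept. Both knockout embryos profiled here lack the R26 EYFP allele that all control embryos carry, and so genotype and EYFP allele cannot be told apart within this population. A covariate for the allele takes its effect from the single Ter119- CD71+ array of embryo 1, whose sex-linked genes also differ. The covariate assumes the same effect in both populations. With it 17 genes were called, all 17 of them higher and shared, among them Trim30a, Sp100, Rtp4, Samd9l, Slc7a11 and Slc7a3. Of the genes that lost the call, some kept folds near their size, as did Hsd3b6 at -2.30 (adjusted p = 0.0920), Runx1t1 at -1.85 (adjusted p = 0.0610), Serpina6 at -2.29 (adjusted p = 0.223) and Ifi27 at 3.08 (adjusted p = 0.154). Others shrank, as did Hbb-bh1 from -1.77 to -0.87, Nfe2 from -0.74 to -0.39 and Dhx58 from 1.45 to 0.66 (adjusted p = 0.999, 0.999 and 0.929).

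**Figure D2:**
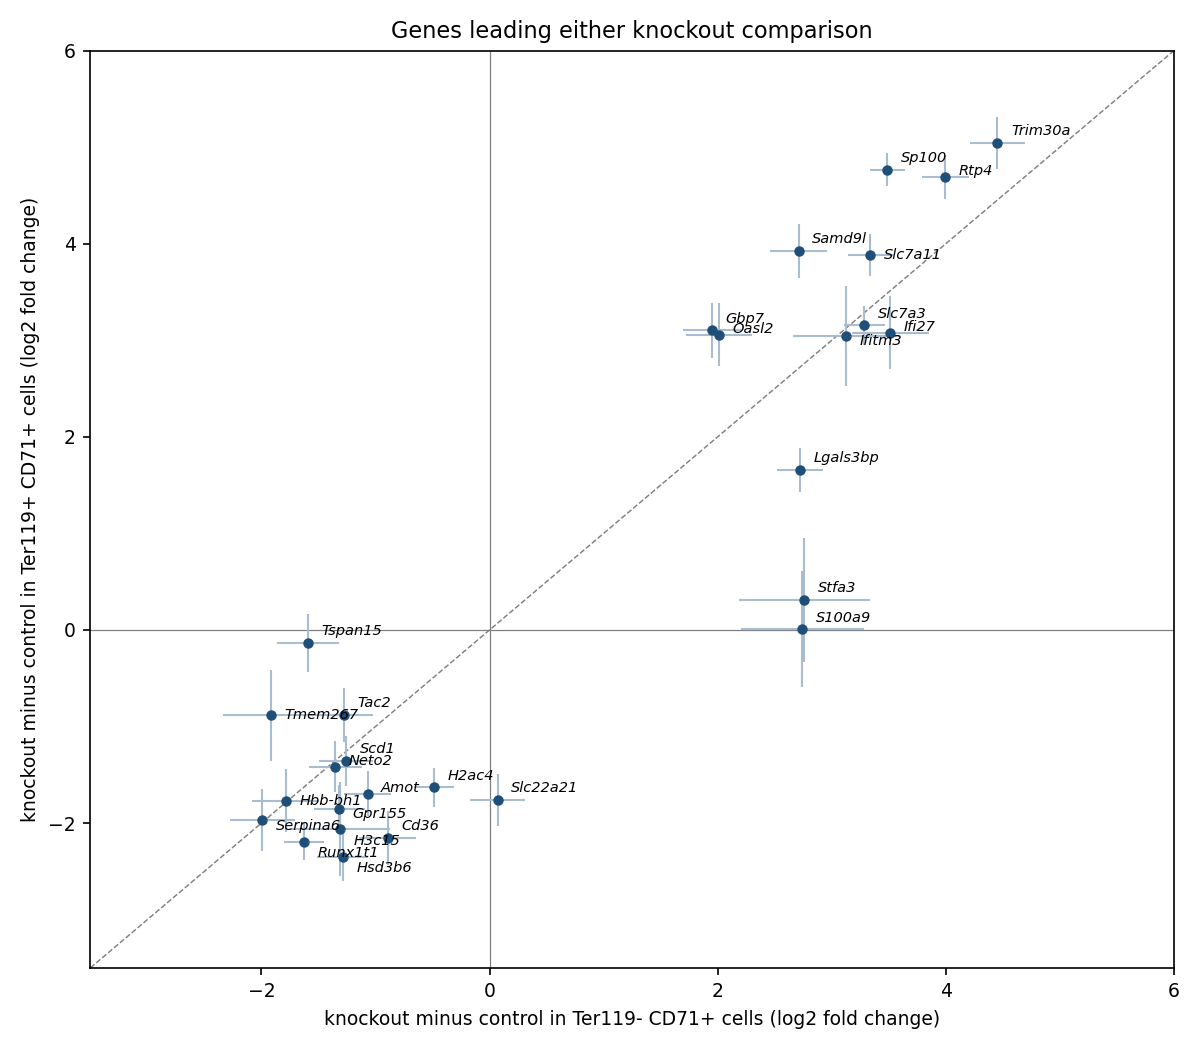
Log2 fold change between knockout and control in Ter119- CD71+ cells (x axis) and Ter119+ CD71+ cells (y axis) for the 28 genes that led either comparison; bars are standard errors and the dashed line marks equal effects. Of these, 27 have the same sign in both populations, while S100a9, Tspan15 and Stfa3 lie at 0.01, -0.13 and 0.31 in Ter119+ CD71+ cells, and Slc22a21 lies at 0.07 in Ter119- CD71+ cells.

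Whether the knockout effect differs between the populations was tested as an interaction, and 2 genes passed. Adgrg7, an adhesion G protein-coupled receptor gene, was 8.44 ± 0.13 in knockout and 5.77 ± 0.12 in control Ter119- CD71+ cells (n = 3 each), against 5.69 ± 0.32 (n = 2) and 5.06 ± 0.13 (n = 3) in Ter119+ CD71+ cells, an interaction of -2.05 (SE 0.21, adjusted p = 0.00278). Mpped2 was 6.54 ± 0.11 and 5.13 ± 0.03 in Ter119- CD71+ cells, against 5.02 ± 0.01 and 4.82 ± 0.18, an interaction of -1.20 (SE 0.16, adjusted p = 0.0393). Of 19938 genes 1087 had an unadjusted p under 0.05. The count was 12 without the Ter119+ CD71+ array of knockout embryo 11 and 1 without knockout embryo 11, control 2, control 13 or control 15 among the Ter119- CD71+ arrays or knockout 10 or control 15 among the Ter119+ CD71+ arrays. The Mpped2 call ended in 8 of 11 omissions (highest adjusted p 0.161), all except those of the Ter119- CD71+ array of knockout embryo 10 and the Ter119+ CD71+ arrays of control embryo 2 and knockout embryo 11. It also ended, at -1.15, with embryo as a fixed block and with the EYFP covariate (adjusted p = 0.107), while Adgrg7 stayed called under both.

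The knockout effects in the 2 populations correlated across genes at r = 0.58 (rho 0.41; genes are not independent replicates). The 2 comparisons share no array but share embryos. In 100 simulated sets without an effect r was at most 0.105 in size. Their noise was independent between genes, so that range can be too narrow. Of the called genes, 97 were higher in both populations, where independent lists would share 3.99, and 53 were lower in both, where they would share 1.84. All comparisons use the same estimate of spread for each gene, so calls are not independent and such expectations, here and below, can be too low. No gene was called in opposite directions. Of the 28 leading genes 19 were called in both in the same direction, among them Trim30a, Sp100, Rtp4, Slc7a11, Slc7a3, Runx1t1 and Serpina6.

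In controls, the change from Ter119- CD71+ to Ter119+ CD71+ cells shows what maturation alters in embryos with 1 floxed and 1 intact Adar allele. Late erythroid genes rose. The steroid dehydrogenase gene Hsd3b6 rose by 4.54 (SE 0.22, adjusted p = 3.20e-08), Tcp11l2 by 4.31 (SE 0.33), Xpo7 by 3.77 (SE 0.16, adjusted p = 1.59e-08) and Ypel4 by 3.22 (SE 0.21). Dctd fell by 3.52 (SE 0.33), and the progenitor genes Kit, the stem cell factor receptor, and Cdk6 fell by 3.05 (SE 0.18, adjusted p = 1.81e-07) and 2.97 (SE 0.20, adjusted p = 5.04e-07). Of 24 late erythroid maturation genes 21 rose and 1 fell, also when adjusted over the list alone (mean 1.07, adjusted p = 1.33e-17; adjusted p = 0.0103 with an estimated correlation). Of 27 G2/M genes 23 rose (25 when adjusted over the list alone; mean 0.65, adjusted p = 1.70e-16; adjusted p = 0.105 with an estimated correlation). Of 20 red cell membrane genes 19 rose (19 when adjusted over the list alone; mean 0.88, adjusted p = 1.30e-15; adjusted p = 0.143 with an estimated correlation), and so did 5 of 6 globin genes (5 when adjusted over the list alone; mean 1.64, adjusted p = 7.04e-07; adjusted p = 0.0640 with an estimated correlation).

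Among heme genes 11 of 18 rose and 1 fell in this step, with 13 and 1 when adjusted over the list alone (mean 0.47, adjusted p = 1.17e-05; adjusted p = 0.245 with an estimated correlation). Of 22 early progenitor genes 6 fell and 1 rose, with 8 and 1 when adjusted over the list alone (mean -0.49, adjusted p = 0.0112; adjusted p = 0.284 with an estimated correlation). Of 45 ribosomal protein genes 8 fell and 0 rose, the same numbers as when adjusted over the list alone (mean -0.24, adjusted p = 3.31e-05; adjusted p = 0.284 with an estimated correlation). Erythroid transcription factors had 7 higher and 4 lower of 20, and 12 and 5 when adjusted over the list alone (mean 0.25, adjusted p = 0.0234, and 0.108 without the Ter119- CD71+ array of control embryo 2; adjusted p = 0.473 with an estimated correlation). Markers of other cells moved as well. Hepatocyte genes had 9 of 19 higher, also when adjusted over the list alone (mean 0.47, adjusted p = 3.00e-05; adjusted p = 0.245 with an estimated correlation). Megakaryocyte genes had 4 of 12 higher, 5 when adjusted over the list alone (mean 0.33, adjusted p = 0.0242; adjusted p = 0.245 with an estimated correlation). The interferon-stimulated list was not called (mean 0.19, adjusted p = 0.0840), except on arrays quantile-normalized again and in 2 omissions of 1 array. limma called 3789 genes, 1449 higher and 2340 lower, and 3720 of them did not overlap, as did 34.5% of all genes where chance gives 10%.

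The later step, from Ter119+ CD71+ to Ter119+ CD71med cells, was measured in controls alone. The embryonic globin gene Hbb-y rose by 2.72 (SE 0.39, adjusted p = 0.000762), Ang6, of the angiogenin family, by 2.06 (SE 0.16, adjusted p = 7.04e-05) and Tcp11l2 by 2.01 (SE 0.37). The interferon-stimulated genes Ifit1 and Rsad2 rose by 2.18 (SE 0.33) and 2.16 (SE 0.40), the latter not without the Ter119+ CD71med array of embryo 15 (adjusted p = 0.0682). Ttc27 fell by 2.08 (SE 0.35), Slc38a1, a glutamine transporter gene, by 1.97 (SE 0.18, adjusted p = 7.04e-05) and Scpep1 by 1.88 (SE 0.23). G1/S genes fell, 19 of 27 with 0 higher, also when adjusted over the list alone (mean -0.59, adjusted p = 1.63e-14; adjusted p = 0.160 with an estimated correlation). Of 45 ribosomal protein genes 12 fell with 0 higher, 15 lower when adjusted over the list alone (mean -0.31, adjusted p = 1.50e-10; adjusted p = 0.160 with an estimated correlation).

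Globins continued upward in this step, with 4 of 6 higher and 5 when adjusted over the list alone (mean 1.31, adjusted p = 4.19e-06; adjusted p = 0.160 with an estimated correlation). Late erythroid genes did too, with 9 higher and 2 lower of 24, and 15 and 2 when adjusted over the list alone (mean 0.43, adjusted p = 2.00e-05; adjusted p = 0.160 with an estimated correlation). Interferon-stimulated genes had 9 higher and 2 lower of 54, and 10 and 2 when adjusted over the list alone (mean 0.35, adjusted p = 0.00373, and 0.0610 without the Ter119+ CD71+ array of embryo 2; adjusted p = 0.577 with an estimated correlation). Hepatocyte markers had 5 of 19 higher, also when adjusted over the list alone (mean 0.44, adjusted p = 0.000180; adjusted p = 0.357 with an estimated correlation). Megakaryocyte markers had 3 of 12 higher, with 5 when adjusted over the list alone (mean 0.34, adjusted p = 0.0112, and 0.0663 without the Ter119+ CD71med array of embryo 15; adjusted p = 0.182 with an estimated correlation). The myeloid list was at 5.74 ± 0.04 in Ter119+ CD71med (n = 2) and 5.26 ± 0.09 in Ter119+ CD71+ cells (n = 3), and was not called (adjusted p = 0.0587). limma called 2656 genes, 820 higher and 1836 lower. That is 30.9% higher, against 44.0% on arrays quantile-normalized again and 20.8% on median-centred arrays. Of them 2654 did not overlap, as did 44.0% of all genes where chance gives 20%. The count was 1528 without the Ter119+ CD71+ array and 867 without the Ter119+ CD71med array of embryo 15.

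**Figure D3:**
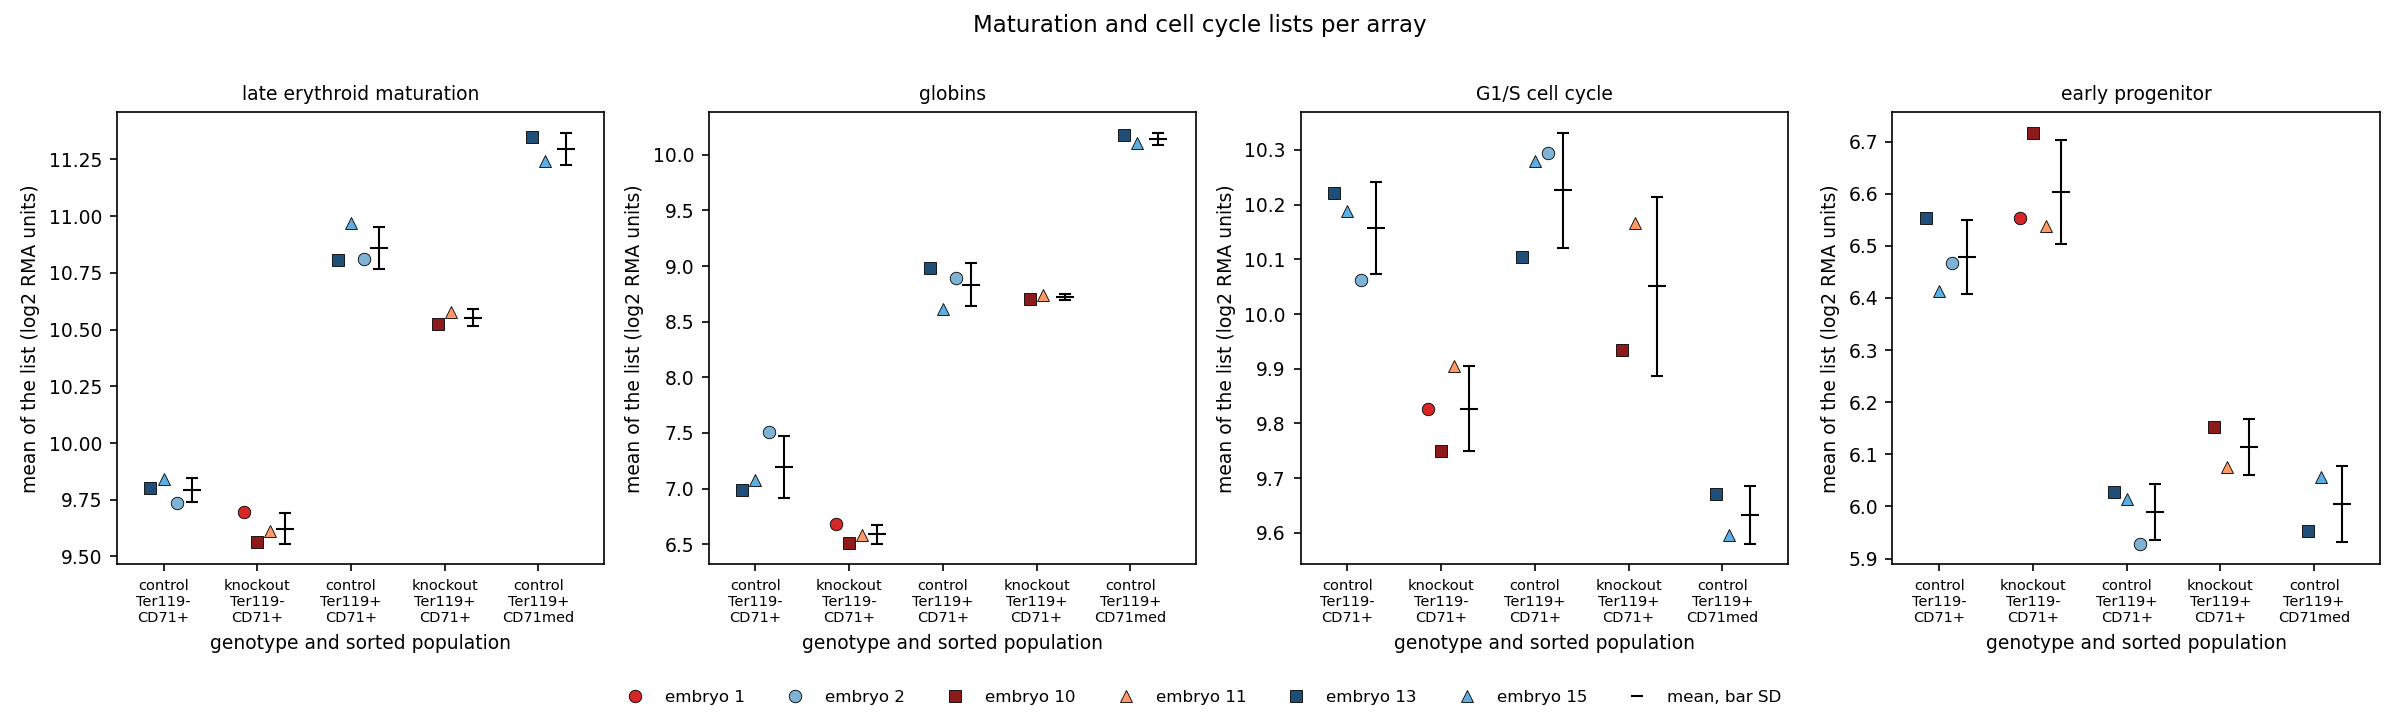
Mean of 4 gene lists on each array in log2 units, by genotype and sorted population; points are arrays marked by embryo, and bars are the group mean with its SD. Late erythroid and globin means step up from Ter119- CD71+ to Ter119+ CD71med cells, and in control cells the G1/S mean is 10.16, 10.23 and 9.63 in the 3 populations.

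In knockout embryos, the step from Ter119- CD71+ to Ter119+ CD71+ cells carried much of the control pattern. Hbb-y rose by 3.89 (SE 0.39, adjusted p = 3.99e-05), Ypel4 by 3.49 (SE 0.23), Hsd3b6 by 3.48 (SE 0.25), and the interferon-stimulated genes Rsad2 and Ifit1 by 3.22 (SE 0.40) and 3.05 (SE 0.33). Dctd fell by 3.27 (SE 0.37), Kit by 2.96 (SE 0.21), Cdk6 by 2.92 (SE 0.22) and Adgrg7 by 2.75 (SE 0.15). The myeloid genes Lyz2 (-2.83, SE 0.66) and S100a9 (-2.69, SE 0.60) fell, calls that ended without the Ter119+ CD71+ array of embryo 10 (adjusted p = 0.185 and 0.0572). Late erythroid genes rose, 18 of 24, with 21 when adjusted over the list alone (mean 0.93, adjusted p = 2.37e-17; adjusted p = 0.0108 with an estimated correlation). So did 5 of 6 globin genes, 6 when adjusted over the list alone (mean 2.13, adjusted p = 1.05e-10; adjusted p = 0.0161 with an estimated correlation).

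Red cell membrane genes rose in the knockout step, 15 of 20, with 18 higher and 1 lower when adjusted over the list alone (mean 0.76, adjusted p = 1.09e-14; adjusted p = 0.160 with an estimated correlation). So did 15 of 27 G2/M genes, 24 when adjusted over the list alone (mean 0.53, adjusted p = 2.45e-14; adjusted p = 0.152 with an estimated correlation). Interferon-stimulated genes had 14 higher and 2 lower of 54, and 17 and 4 when adjusted over the list alone (mean 0.43, adjusted p = 0.000299; adjusted p = 0.437 with an estimated correlation). Heme genes had 9 higher and 1 lower of 18, and 10 and 1 when adjusted over the list alone (mean 0.44, adjusted p = 1.93e-05; adjusted p = 0.295 with an estimated correlation). Early progenitor genes had 7 lower and 1 higher of 22, also when adjusted over the list alone (mean -0.49, adjusted p = 8.49e-05; adjusted p = 0.173 with an estimated correlation). Ribosomal proteins had 5 lower of 45, with 8 when adjusted over the list alone (mean -0.24, adjusted p = 1.95e-06; adjusted p = 0.295 with an estimated correlation). The myeloid list fell with 4 of 19 genes lower, 8 when adjusted over the list alone (mean -0.84, adjusted p = 1.93e-05; adjusted p = 0.437 with an estimated correlation). G1/S genes (4 of 27 higher, also when adjusted over the list alone; mean 0.22, adjusted p = 0.00143), erythroid transcription factors (8 higher and 3 lower of 20, 9 and 3 when adjusted over the list alone; mean 0.27, adjusted p = 0.00513) and hepatocyte markers (1 of 19 higher, also when adjusted over the list alone; mean 0.29, adjusted p = 0.0210) were called too, with adjusted p = 0.524, 0.437 and 0.524 with an estimated correlation. The first 2 lost that call without the Ter119+ CD71+ array of embryo 11 (adjusted p = 0.610 and 0.230), and the third without the Ter119- CD71+ array of embryo 1 or the Ter119+ CD71+ array of embryo 10 (highest adjusted p 0.536).

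For the knockout step limma called 2143 genes, 898 higher and 1245 lower, of which 2142 did not overlap, as did 35.0% of all genes where chance gives 20%. The count was 1156 without the Ter119+ CD71+ array of embryo 10, where most were higher (707 higher and 449 lower), 1421 without the Ter119- CD71+ array of embryo 11 and 3357 without the Ter119+ CD71+ array of embryo 11. Across genes the step correlated with the control step at r = 0.82 (rho 0.65). In the simulated sets, with noise independent between genes, r was at most 0.0921 in size. Of the called genes 762 were higher in both, where independent lists would share 65.3, 1050 were lower in both, against 146, and 1 went in opposite directions.

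Whether the knockout effect lies along the control maturation difference was asked with contrasts that share no array but share control embryos. The simulated sets used the consensus correlation of 0.00385 for arrays of 1 embryo, where single pairs ran from -0.23 to 0.35. In Ter119+ CD71+ cells the knockout effect was set against the control change from Ter119- CD71+ to Ter119+ CD71med cells. Across genes they correlated at r = -0.18 (rho -0.06, slope -0.07), with a covariance of -0.0402. In 100 simulated sets without an effect the mean covariance was -4.69e-05 and r reached 0.0661 in size. Their noise was independent between genes, so that range can be too narrow. The correlation was -0.42 without the Ter119+ CD71+ array of knockout embryo 10, -0.11 without that of control embryo 2 and 0.04, the opposite sign, without that of knockout embryo 11. Of the called genes 199 were higher in the knockout and lower along the axis, where independent lists would share 59.3, and 157 were lower in the knockout and higher along it, against 38.9. Another 26 were higher in both and 13 lower in both, against 53.4 and 43.2. On this axis, where control Ter119- CD71+ cells lie at 0 and control Ter119+ CD71med cells at 1, knockout Ter119+ CD71+ cells lay at 0.485 ± 0.129 (SD, n = 2) and control cells at 0.558 ± 0.0562 (n = 3). An exact two-sided permutation test gave p = 0.5, and the smallest p it can give here is 0.1.

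In Ter119- CD71+ cells the knockout effect was set against the control change from Ter119+ CD71+ to Ter119+ CD71med cells. They correlated at r = 0.30 (rho 0.30, slope 0.22), with a covariance of 0.0313. In the simulated sets, with noise independent between genes, the mean covariance was -0.000131 and r reached 0.0974 in size. Of the called genes 40 were higher in both, where independent lists would share 11.1, and 40 lower in both, against 15.7. Another 23 were higher in the knockout and lower along the axis, against 24.9, and 13 the other way, against 7.03. On this axis, with control Ter119+ CD71+ cells at 0 and Ter119+ CD71med cells at 1, the knockout arrays lay at -0.472 ± 0.0940 and the control arrays at -0.688 ± 0.0507 (n = 3 each). All 3 knockout arrays lay above all 3 control arrays (exact two-sided permutation p = 0.1, the smallest that 3 arrays against 3 can give). The interferon-stimulated list and the myeloid mean, higher in these knockout cells by 0.92 and 0.98, were also higher along this axis, the latter not called. The G1/S list was lower in both. Late erythroid and globin lists rose along the axis but were lower in the knockout cells, so the position is no measure of erythroid maturity.

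**Figure D4:**
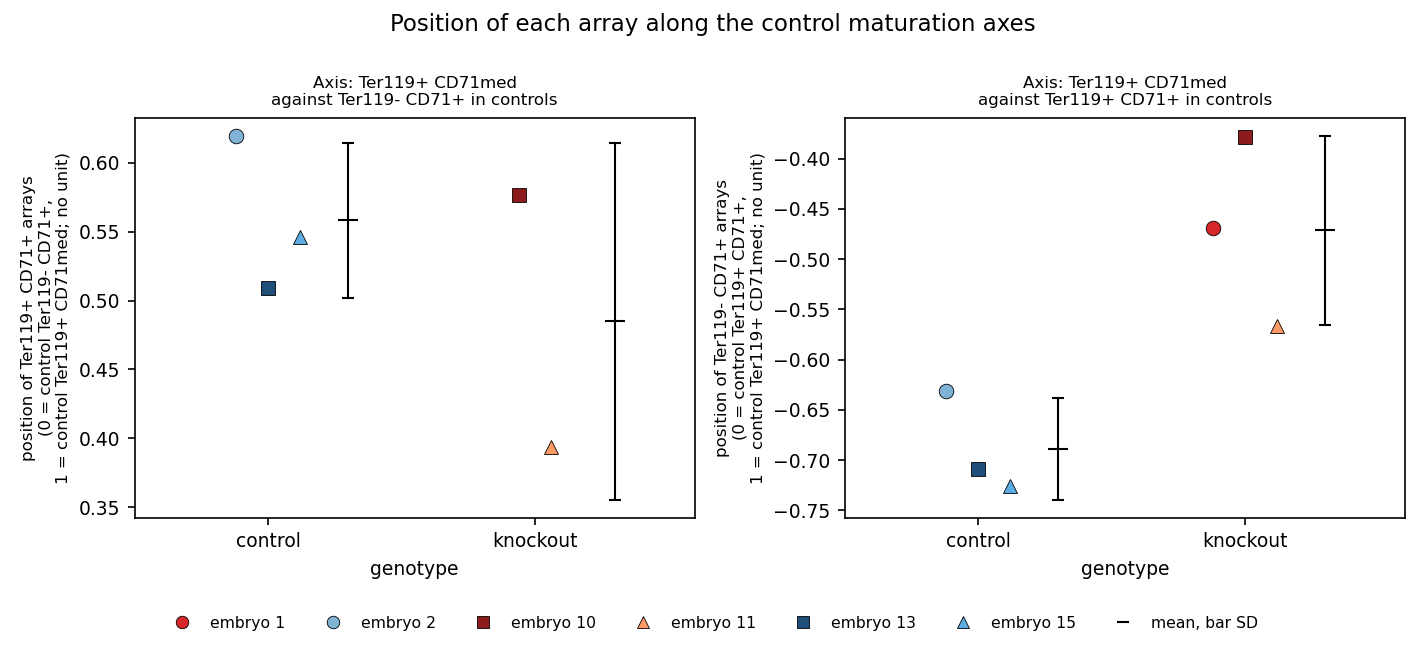
Position of each array along the control maturation axes, in units of the control difference that defines each axis, with the group mean and SD as bars. In Ter119+ CD71+ cells knockout embryo 10 lies at 0.576 among the controls and embryo 11 at 0.393 below them, while in Ter119- CD71+ cells the knockout arrays lie above the control arrays.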

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

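The tests of myeloid cells, of a mislabelled sample and of the brightness of the Adar probe set, and that of the R26 EYFP genotype in Ter119+ CD71+ cells, were chosen only after the result was seen; the condition that a rise exceed the control SD in the EYFP test was added then too.

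A difference between the 2 populations in the knockout effect, by the interaction test, marked 2 genes and 10 lists. The genes are Adgrg7, at -2.05, and Mpped2, at -1.20. The lists, all with 0 members called, are neutrophil and myeloid markers (mean -0.92, adjusted p = 2.76e-10), macrophage markers (-0.39, adjusted p = 7.93e-05), late erythroid maturation (-0.14, adjusted p = 0.00246), G2/M (-0.12, adjusted p = 0.00313), hepatocyte markers (-0.18, adjusted p = 0.00337), G1/S (0.16, adjusted p = 0.0228), red cell membrane (-0.12, adjusted p = 0.0339), RNA editing (0.26, adjusted p = 0.0362), interferon-stimulated genes (0.24, adjusted p = 0.0444) and interferon genes with their receptors (-0.14, adjusted p = 0.0447). With an estimated correlation none of the 10 was called (adjusted p from 0.287 to 0.749), and fry called none. Only the neutrophil and macrophage lists kept the call in all 11 omissions of 1 array.

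Signals also appeared in probe sets that the gene tests did not use. Among the 1621 with several gene symbols, 24 were called between knockout and control in Ter119- CD71+ cells (21 higher and 3 lower) and 21 in Ter119+ CD71+ cells (11 higher and 10 lower). Among the 12146 with no listed gene, 38 were called in Ter119+ CD71+ cells (10 higher and 28 lower) and 0 in Ter119- CD71+ cells. A test for an outlying sample within a group was not run, since no group has 4 samples.

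Neutrophil and myeloid markers were higher by 0.98 in knockout Ter119- CD71+ cells, most in embryo 10. Within groups the 19 markers varied together over the arrays, as myeloid cells in the sorted population would predict. Their mean residual correlation was 0.640, above all 1000 random lists of genes matched on mean level (95th percentile 0.281). Embryo 10 stood furthest from its group, at a list mean of 6.98 against 5.76 and 5.71 in embryos 1 and 11. A joint rise of these genes in the cells of that embryo would give the same, so the test does not decide between them. The test of the R26 EYFP genotype did not decide. Embryo 1, which carries the reporter allele as the controls do, rose by 0.585, against a control SD of 0.208. That is 49.8% of the mean rise of 1.18 in the other 2, which rests mostly on embryo 10. Embryo 11, which also lacks the allele, lay at 5.71, below embryo 1 at 5.76, and the controls lay at 5.41 or lower. Among the knockout embryos the level did not follow the EYFP genotype, but 1 knockout embryo with the allele does not settle the question. That embryo also differs from the other 2 in its sex-linked genes. A change in the share of myeloid cells caused by the knockout stays open and was not tested.

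The Adar probe set was not lower in knockout cells. Its mean level of 7.79 lies at percentile 76.0 of all genes, which argues against a dim or saturated probe set. Of the 5 knockout arrays, 0 lay inside the control range of the interferon-stimulated list, where a control sample labelled as a knockout would lie, which argues against a mislabelled sample among them. That separation is the result of the report seen again, under the same labels. Whether the probes lie outside the deleted part of the gene stays open, because 1 probe set carries the gene and its probe positions were not used here.

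Of the 10 ways to split the 6 Ter119- CD71+ arrays into 3 and 3, only the real split gave 441 called genes. The highest count of the others was 0. Of the 10 splits of the 6 control arrays of the first maturation step, only the real split gave 3789, and the highest of the others was 0. Every other split mixes the genotypes or populations within its groups, so a low count there was likely in advance. The splits are too few for a share under 0.05.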

How the results depend on the processing

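The covariate made of the myeloid marker mean was chosen only after the result was seen, and so was the rule that sets a shift of an axis correlation against the SD of its values with 1 array left out. Over all alternatives 60 gene counts stayed within 1.5 times the reported one, 33 were lower and 7 higher, and 693 list results kept direction and call, 165 lost the call, 3 gained it and 3 turned. Unless fewer arrays or a stricter limit shows it, the cause was not tested.

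For knockout against control in Ter119- CD71+ cells the count was 286 on median-centred arrays, 3151 with array weights, 148 at a log2 fold change of at least 1, 33 with the R26 EYFP genotype as a covariate and 25 with the myeloid covariate, and it ran from 135 to 1006 with 1 array left out. In Ter119+ CD71+ cells it was 116 with only the groups compared, 128 with array weights, 190 at a log2 fold change of at least 1, 17 with the EYFP covariate and from 162 to 1546 with 1 array left out. The interaction gave 1 gene after quantile normalization, on median-centred arrays, with only the groups compared and with array weights, 4 with embryo as a fixed replicate block (1 of them, Adgrg7, shared) and from 1 to 12 with 1 array left out. The first control step gave 6349 with array weights and 1081 at a log2 fold change of at least 1. The second gave 485 at that limit and from 867 to 2892 with 1 array left out. The knockout step gave 1007 with array weights, 635 at that limit and from 1156 to 3357 with 1 array left out. With embryo as a random replicate block the knockout counts were 441 and 510, as without it.

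The interferon-stimulated list kept its means of 0.92 and 1.16 with an estimated correlation and lost its call (adjusted p = 0.0580 and 0.0653), since that test allows for the correlation between genes. Adar in Ter119+ CD71+ cells was -0.00754 on median-centred arrays, -0.0780 with array weights and -0.15 with the EYFP covariate. With 1 array left out it ran from -0.16 to 0.31 there, from -0.28 to 0.0190 in Ter119- CD71+ cells, from -0.0719 to 0.40 for the interaction and from -0.0261 to 0.45 for the first control step. The G1/S list ran from 0.0396 to 0.27 for the interaction. With the myeloid covariate the G2/M list was -0.0224 with its test pointing up, not called, and the early progenitor list turned to -0.0332, not called, in Ter119- CD71+ cells; the globin, heme, late erythroid and macrophage lists lost their calls. The axis correlation in Ter119- CD71+ cells was 0.23 after quantile normalization, 0.40 over called genes alone and from 0.26 to 0.33 with 1 array left out. That in Ter119+ CD71+ cells ran from -0.42 to 0.0352. An omission that leaves a group with 1 array assumes that it varies like the other groups.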

Other observations

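The list of hypoxia-inducible and glycolytic genes and its tests against myeloid cells and, in Ter119+ CD71+ cells, the EYFP genotype were chosen only after the result was seen, so the list is not independent evidence.

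Genes that respond to low oxygen, with genes of glycolysis, were higher in knockout cells of both populations. In Ter119- CD71+ cells 20 of 44 rose and 0 fell. They include Bnip3, a mitophagy receptor gene, at 2.55 (SE 0.18), Pfkp, a phosphofructokinase gene, at 2.54 (SE 0.19), the adenylate kinase gene Ak4 at 2.23 (SE 0.15; 1.32 by its other probe set), Hk2 (hexokinase 2) at 1.89 and P4ha1, a prolyl hydroxylase subunit of collagen synthesis, at 1.45 (SE 0.13). Of the same list 16 rose and 0 fell in Ter119+ CD71+ cells, among them Pfkp at 2.91 (SE 0.21), Ak4 at 2.11 (SE 0.16; 0.89 by its other probe set), P4ha1 at 2.02 (SE 0.15), Aldoa (aldolase A) at 1.93 (SE 0.14) and Vegfa at 1.45. The list mean was 8.50 ± 0.21 in knockout and 7.77 ± 0.06 in control Ter119- CD71+ cells (SD, n = 3 each), and 8.24 ± 0.08 (n = 2) against 7.56 ± 0.03 (n = 3) in Ter119+ CD71+ cells. No member passed the interaction test in limma, but only 2 of all 19938 genes did (1087 at an unadjusted p under 0.05). This does not show an equal effect in both populations. The members with the smallest unadjusted p were Aldoa, with an interaction of 0.96, and Slc2a1, with -0.89.

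The R26 EYFP genotype as the whole source of the rise in Ter119- CD71+ cells is argued against by embryo 1, which has the genotype of the controls and rose by 0.683, 89.9% of the mean rise of 0.759 in the other 2 (control SD 0.0625), though this rests on 1 embryo. Embryo 1 also differs from those 2 in its sex-linked genes. In Ter119+ CD71+ cells 0 knockout arrays have the EYFP genotype of the controls, so the R26 EYFP genotype and the knockout cannot be told apart there. Less mature cells in the knockout Ter119+ CD71+ sort would shift the list by 0.0318 from their mean position on the maturation axis. The observed shift was 0.68, with 0.117 between the 2 knockout embryos. That position was 0.576 in embryo 10 and 0.393 in embryo 11. It is a projection over all genes, among them interferon-stimulated genes, whose list mean was also higher at the mature end of the control axis. The position is therefore no sure measure of maturity. Myeloid cells in that sorted population are argued against by a marker shift of 0.0543, where Ter119- CD71+ cells had 0.98. With the myeloid covariate the list mean went from 0.73 (SE 0.0929) to 0.45 (SE 0.0425) in Ter119- CD71+ cells and from 0.68 to 0.66 in Ter119+ CD71+ cells, and with the EYFP covariate it was 0.68 and 0.60. A response of the knockout cells to oxygen or metabolism is a hypothesis that these data do not test.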
